A study of Rattus norvegicus with 15 samples.

How the data were processed

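Transcript levels were measured on 15 arrays, 3 in each of 5 groups: isolated proximal tubules of rats given saline, 2 mg/kg cisplatin or 10 mg/kg cisplatin, and whole kidneys of rats given saline or 10 mg/kg cisplatin. Per the labels' protocols, the animals were male Wistar/ST rats, the drug or saline was injected intraperitoneally, the tubules were picked under a microscope, and digoxigenin-labelled cRNA made from total RNA was hybridised to the 1-colour, chemiluminescent Rat Genome Survey array of Applied Biosystems. The time between injection and sampling is not given in the sources used here. The labels do not say in words that each array stands for a separate animal, so the p-values measure the spread between these arrays.

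The deposited file of each array holds 1 intensity per probe on a linear scale, per the file headers and values. No header or label states the scanner software, a background correction or a spot filter, and no detection or background column is present. The files listed between 26207 and 26547 of 26857 probes, and the probes absent from a file lay low where other files listed them, at a median signal percentile of 23.1. Signals ran from 4.35 to 3516337 and array medians from 201 to 470, a ratio of 2.34, so the intensities were not scaled to a common median. The series table deposited by the authors holds 1219 probes as a ratio: in all 15 columns each value equalled the file's signal divided by 1 constant per array, within a relative tolerance of 0.000001, with constants between 195.1 and 445.8. Each constant lay within 1 rank of the array's median when absent probes were placed below it. Its column medians lay between 2.58 and 9.46. The scale of that table is therefore known, and the rule by which its probes were chosen is not given in the sources used here.

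A gene symbol was available for probes of the series table: 401 probes had 1 symbol, 2 had several and were not named, and 26454 had none. All 401 were matched by Entrez identifier to the RefSeq gene table of assembly GRCr8, with 0 symbols updated and 0 genes with more than 1 named probe. All named genes therefore belong to the 1219 probes of the authors' series table. Because the rule behind that choice is unknown and may have used these samples, counts and tests over named genes and gene lists cannot be taken as independent evidence of their direction. The platform's other probes enter the counts without a name. Among the genes fixed by name before the data were examined, Clu, Mdm2, Slc22a2, Slc47a1, Slc31a1, Egf, Umod, Lrp2, Aqp2 and Slc12a3 have no named probe here.

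Signals were taken to log2 and quantile normalized over the 15 arrays with limma 3.58.1 in R 4.3.3. Without a background column no background correction was applied, and without a detection column no filter on dim probes. Probes with at least 2 values in each group were tested (26601, leaving out 256). A mean per group was fitted with lmFit over all 15 arrays, and 6 contrasts were tested with eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The fit had 10 residual degrees of freedom, a prior of 3.92 degrees of freedom and a prior SD of 0.56 on the log2 scale. Fold changes carry the standard error of the fit, and means carry the SD over 3 arrays. The number of arrays limits the precision: the median residual SD on the log2 scale was 0.35 in the brightest of 4 equal groups of probes and between 0.71 and 0.81 in the other 3.

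The text names the 8 largest rises and 8 largest falls per comparison among genes past the threshold whose groups did not overlap in any array, up to 4 members of smallest adjusted p per list described, and a set of genes named in advance. This rule, the 28 gene lists, the design and most alternatives were fixed before the data were examined. Of 688 genes in the lists 83 had a named probe. Lists with at least 3 named members numbered 14, lists with 1 or 2 numbered 4, and 10 had none, among them every list of glomerular, endothelial, distal tubule, collecting duct, stromal and erythroid markers. Lists were tested with camera, preset correlation 0.01, within 398 named probes that had all 15 values, a background chosen after the files were seen, since unnamed probes can belong to no list. Camera with an estimated correlation and fry were run beside it. The chemokine list had fewer than 3 members with all values and was described without a list test.

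The fit was tested on simulated data built from the real probes' means and spreads, with 200 of 26601 probes changed at 2 mg/kg in each of 5 rounds. It called 0.896% of probes changed 2-fold, 29.6% of those changed 4-fold and 63.9% of those changed 8-fold, and 2.56%, 72.5% and 93.1% in the brightest of 4 equal groups. Among all simulated calls 3.69% were false. In 20 simulated rounds the list test found the shifted list 20 times and called 3 of 280 unshifted lists. The simulated genes varied independently of each other, whereas real members can correlate, with an estimated correlation of 0.516 for the tubular injury markers. These rounds therefore do not test the camera p-values of such lists. Alternatives covered other scalings, filters, the series table's values, the arrays in the fit, the variance model, array weights, size thresholds, the replicate number as a block and leaving out each array. Background correction with normexp at an offset of 50 and a restriction to the brighter part of the probes were added after the data were seen. The median log2 change of all probes lay more than 0.1 from 0 only where arrays were not scaled or were centred on their medians: without scaling it was -0.13 in tubules at 2 mg/kg, -0.32 at 10 mg/kg, -0.14 between the doses, 0.61 between control tubules and control whole kidneys and -0.28 for the tissue difference of the drug effect, and with median centring it was 0.11 between the doses.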

Results

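Gene expression was profiled in kidneys of rats after cisplatin, a platinum drug whose use is limited by injury to the proximal tubule, the nephron segment that reabsorbs most of the filtered solutes. Isolated proximal tubules were studied after saline, 2 mg/kg and 10 mg/kg, and whole kidneys after saline and 10 mg/kg, with 3 arrays per group. Within groups the arrays correlated at 0.862 to 0.955 over probes, and between groups at 0.766 to 0.936. No pair of arrays was identical. Control whole kidney replicate 3 stood apart, with a mean correlation of 0.812 to the other arrays.

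The question of the first comparison was which transcripts changed in proximal tubules at 10 mg/kg. Plk2, a p53-responsive polo-like kinase, rose 60.7-fold, and Havcr1, which encodes the tubular injury protein KIM-1, rose 30.7-fold, from a log2 signal of 8.78 ± 0.78 (SD, n = 3) to 13.72 ± 0.34. With no background measure, the folds here and below are ratios of signals. Isg20 and Rsad2, both interferon-stimulated, rose by 4.90 ± 0.43 (SE) and 4.05 ± 0.56 on the log2 scale. The chemokine Ccl20 rose by 4.63 ± 0.59, the scavenger receptor gene Olr1 by 4.61 ± 0.53, S100a6 by 4.07 ± 0.51 and Asns, the asparagine synthetase gene, by 4.02 ± 0.45, from a signal percentile of 8.73 in control tubules that is not known to be above background. The largest falls were in Acmsd, an enzyme of tryptophan catabolism, at -4.81 ± 0.59, the organic anion transporter family member Slc22a25 at -4.25 ± 0.53, the pyruvate carboxylase gene Pc at -3.79 ± 0.45 and Gc, the vitamin D binding protein gene, at -3.78 ± 0.80. Hnmt, Gfra2, Rgn and Thrb fell by 3.72, 3.70, 3.63 and 3.60 on the log2 scale.

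Of 6 named tubular injury markers 5 rose in tubules at 10 mg/kg, and 5 also when adjusted over the list alone. Beside Havcr1 and S100a6 these were Anxa2 (3.30 ± 0.40), Spp1, which encodes osteopontin (3.14 ± 0.58), and Lcn2, which encodes NGAL (3.03 ± 0.51), while Anxa1, named here after its value was seen, stood at 0.80 ± 0.42. The list passed camera in limma (adjusted p = 5.68e-06, adjusted p = 0.123 with an estimated correlation). Among p53 targets Plk2 and Cdkn1a, the p21 gene (3.97 ± 0.57), rose and Cd82 had -1.02 ± 0.29 (limma adjusted p = 0.0511); the list of 3 had a camera adjusted p of 0.0628. All 3 named chemokines rose: Ccl20, Ccl2 (3.61 ± 0.81, 12.2-fold) and Cxcl2 (3.04 ± 0.64). Of 3 immediate early genes Klf6 (2.32 ± 0.30) and Egr2 (2.84 ± 0.72) rose and Ier3 stood at 1.26 ± 0.37, with 3 rising when adjusted over the list alone (camera adjusted p = 0.00672, adjusted p = 0.123 with an estimated correlation). The call of Ccl2 was lost without control tubule replicate 3 (2.92, limma adjusted p = 0.0822) and without 10 mg/kg replicate 2 (3.52, limma adjusted p = 0.0604), and Gc was lost without 10 mg/kg replicate 1 (-3.39, limma adjusted p = 0.0504). Egr2 lost its call without control tubule replicate 2 (2.33) or 3 (2.48) and without 10 mg/kg replicate 1 (2.89), 2 (2.69) or 3 (2.95), with limma adjusted p between 0.0714 and 0.136. Klf6 lost its call without scaling (1.69, limma adjusted p = 0.173), and with only the 6 arrays compared Cxcl2 and Spp1 lost theirs (limma adjusted p = 0.0627 and 0.0592). Gc and Egr2 also lost theirs with only these arrays, and Egr2 further without scaling and with array weights.

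Of 21 named proximal tubule carriers and brush border genes 18 fell, and 21 when adjusted over the list alone (camera adjusted p = 0.00817, adjusted p = 0.460 with an estimated correlation). They included Slc6a13 (-2.93 ± 0.38), Miox (-2.79 ± 0.32), Anpep (-2.75 ± 0.40) and the phosphate transporter gene Slc34a1 (-2.09 ± 0.29). Of 3 drug transporters Slc22a6, which encodes the organic anion transporter OAT1 (-2.54 ± 0.40), and Slc22a5, which encodes the carnitine transporter OCTN2 (-2.32 ± 0.27), fell, and Slc22a7 had -0.87 ± 0.55. Of 7 gluconeogenesis genes 5 fell, with Pc, Slc37a4 (-2.91 ± 0.32) and Fbp1 (-2.53 ± 0.33) among them. Of 8 genes of fatty acid oxidation 3 fell, 6 when adjusted over the list alone, led by Acsm2 (-2.52 ± 0.28) and Amacr (-1.80 ± 0.29). Of 4 hormone axis genes 3 fell, among them the parathyroid hormone receptor gene Pth1r (-2.70 ± 0.37) and the angiotensin receptor gene Agtr1a (-2.41 ± 0.51). The markers of the S1 and S2 segments fell in 5 of 7 cases and those of S3 in 2 of 3. Camera passed none of these last 6 lists at adjusted p between 0.165 and 0.513. Of 6 Nrf2 and glutathione genes Gpx2 rose (2.92 ± 0.35) and Gsta2 fell (-1.58 ± 0.29), and of 4 genes of the integrated stress response Asns rose and Psat1 fell (-2.57 ± 0.35). Of 4 apoptosis regulators Tnfrsf1a rose (1.84 ± 0.28) and Aifm1 fell (-1.47 ± 0.30), and Tnfrsf1a lost its call with median centring (1.53, limma adjusted p = 0.0627) and without scaling (1.14, limma adjusted p = 0.466). With only the 6 arrays compared Agtr1a, Aifm1 and Gsta2 lost theirs (limma adjusted p = 0.0649, 0.104 and 0.0654). The complement genes C1qa and C1qc, the named leukocyte markers, had 1.11 ± 0.40 and 0.94 ± 0.43 (limma adjusted p = 0.153 and 0.292), and 2 of 2 rose when adjusted over the list alone.

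In the limma fit 1553 of 26601 probes changed in tubules at 10 mg/kg, 659 higher and 894 lower. Of the 401 named genes 41 rose and 187 fell, while outside the authors' set of 1219 probes 540 rose and 402 fell. Groups did not overlap for 22.5% of probes, against 10% by chance where each group has 3 values and more where a value is missing. The share of rises was 42.4%, with 341 higher and 737 lower with median centring and 129 higher and 788 lower without scaling. Without control tubule replicate 3 the count was 995, and with only the 6 arrays compared it was 592.

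**Figure D1:**
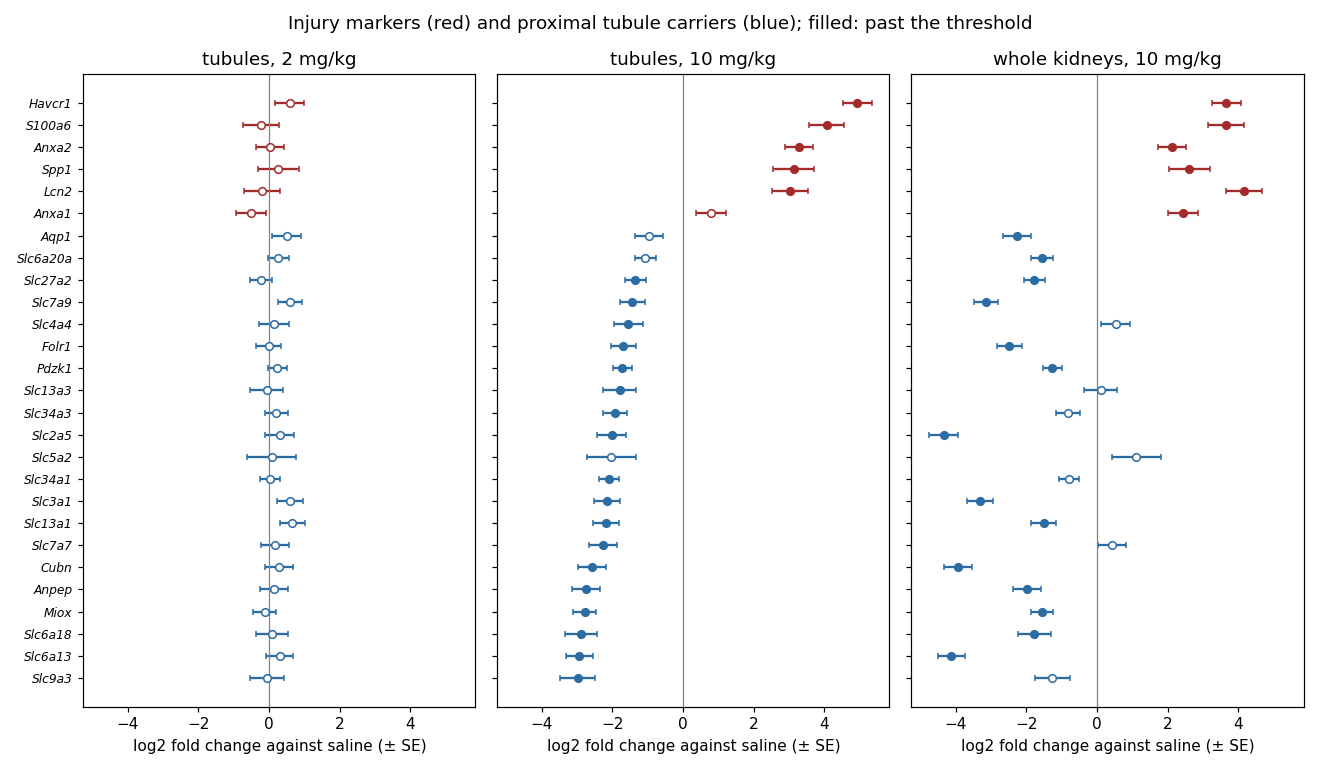
Log2 fold change against saline (x axis, ± SE of the limma fit) of the 6 named injury markers (red) and 21 named proximal tubule carriers (blue), with filled points past the threshold, in tubules at 2 and 10 mg/kg and in whole kidneys at 10 mg/kg. At 10 mg/kg 5 injury markers rose and 18 carriers fell in tubules, 6 rose and 14 fell in whole kidneys, and at 2 mg/kg 0 were past the threshold.

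The question of the second comparison was whether the lower dose changed the tubules. At 2 mg/kg Havcr1 stood at 0.59 ± 0.41 on the log2 scale, Ccl2 at 1.30 ± 0.81, Spp1 at 0.26 ± 0.58, Lcn2 at -0.19 ± 0.51, Cdkn1a at -0.17 ± 0.57 and Slc22a6 at -0.20 ± 0.40. The values farthest from 0 among the list members named were Plk2 (2.26 ± 0.56), Egr2 (2.06 ± 0.72) and Asns (1.73 ± 0.45). Adjusted over the list alone, Plk2, Egr2, Asns and the chaperone gene Hyou1 (-1.22 ± 0.42) passed the threshold. Over all probes the limma fit called 0 of 26601, with a smallest adjusted p of 0.9999, and 903 probes had an unadjusted p under the threshold against 1330 expected by chance. A count below the chance number can come from p-values that run too large, and does not show that there was no response. With the series table's values over its 1219 probes the fit called 23, 13 higher and 10 lower. The rule that chose these probes is not known and may have used these samples, so the 23 are not independent evidence of a response. Groups did not overlap for 12.1% of probes, against 10% by chance where each group has 3 values. Chance is higher for probes with a missing value, so the small excess is not read as a response. No list passed camera.

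Set directly against 2 mg/kg, the tubules at 10 mg/kg had higher Ccl20 (4.98 ± 0.59), Havcr1 (4.36 ± 0.41), S100a6 (4.30 ± 0.51), Isg20 (4.18 ± 0.43), Cdkn1a (4.15 ± 0.57), S100a10 (4.12 ± 0.38), Rsad2 (4.05 ± 0.56) and the glutathione peroxidase gene Gpx2 (3.97 ± 0.35). Acmsd (-5.66 ± 0.59), Slc22a25 (-4.65 ± 0.53), the creatine synthesis gene Gatm (-4.57 ± 0.47), Fmo4 (-4.26 ± 0.43), Galnt11 (-4.20 ± 0.53), Rgn (-4.13 ± 0.48), Aadac (-4.11 ± 0.57) and St6galnac3 (-4.04 ± 0.66) were lower. Lcn2 differed by 3.22 ± 0.51, Spp1 by 2.88 ± 0.58 and Slc22a6 by -2.34 ± 0.40, and Ccl2 by 2.31 ± 0.81 without passing the threshold (limma adjusted p = 0.126). Spp1 lost its call with only the 6 arrays compared (2.86, limma adjusted p = 0.0705). Of the 2 leukocyte markers C1qa and C1qc 0 passed the threshold over all probes, and 2 were higher when adjusted over the list alone. Of the 21 carriers and brush border genes 20 were lower (camera adjusted p = 0.00895, adjusted p = 0.548 with an estimated correlation), and of the 6 injury markers 5 were higher, 6 when adjusted over the list alone (camera adjusted p = 1.78e-06, adjusted p = 0.124 with an estimated correlation).

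The limma fit called 1711 probes between the doses, 707 higher and 1004 lower at 10 mg/kg, of which 42 higher and 203 lower were named. Outside the authors' set of 1219 probes 587 were higher and 503 lower. Over all tested probes 352 were higher and 973 lower with median centring, and 142 and 868 without scaling. The count was 962 without 2 mg/kg replicate 1, 964 without 2 mg/kg replicate 2, and 998 with only the 6 arrays compared. Across probes the log2 fold changes of both doses against the same control tubules correlated at r = 0.268 and rho = 0.279, below the r of 0.499 that simulated unchanged groups gave with shared controls. Their covariance was 0.121 against 0.157 simulated, a difference of -0.0368. The simulated groups held no change, whereas the 10 mg/kg group did, and change at the higher dose alone lowers r. The simulated covariance rests on the spread pooled over all 5 groups. Neither comparison with the simulation therefore decides whether the doses agree. Probes are not independent replicates, and the controls were not split, since with 3 arrays 1 part would hold a single array.

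**Figure D2:**
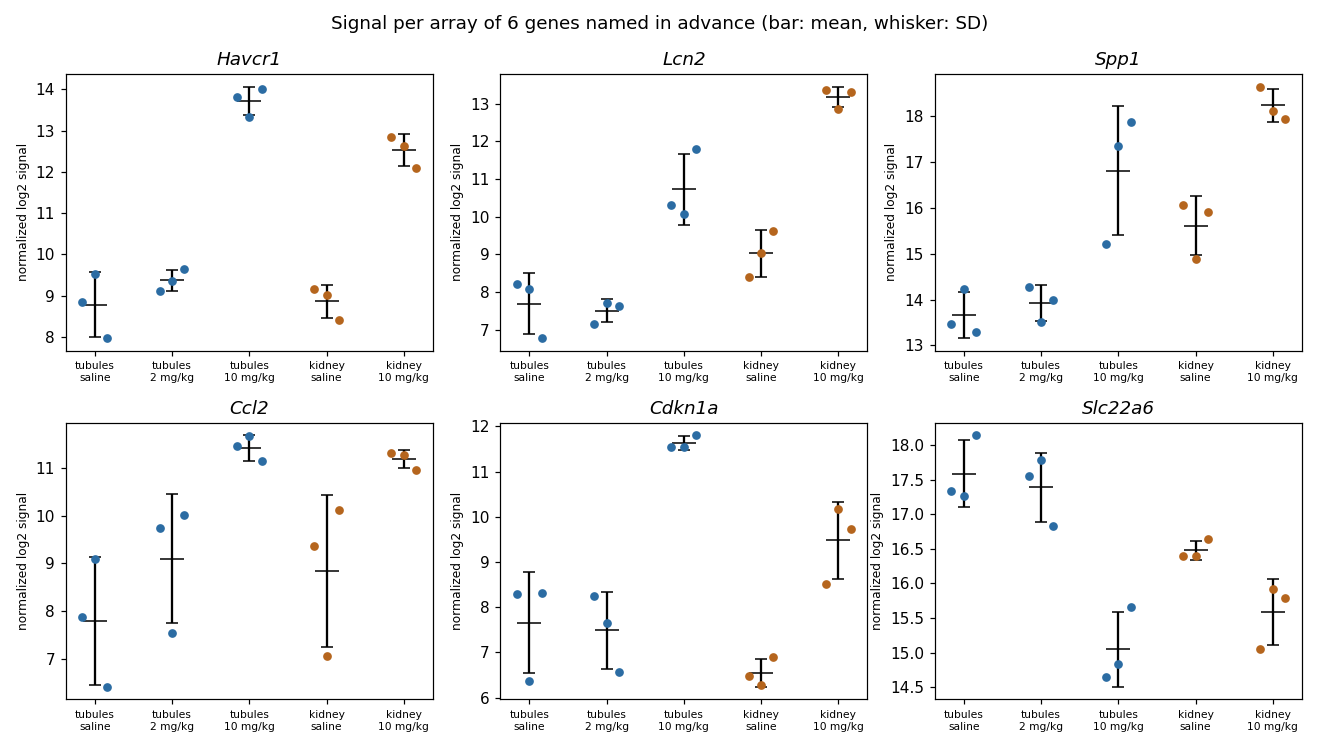
Normalized log2 signal (y axis) of 6 genes named in advance in each of the 15 arrays by group (x axis), with the mean (bar) and SD (whisker) of 3 arrays. Havcr1 lay at 13.72 in tubules and 12.53 in whole kidneys at 10 mg/kg, against 8.78 and 8.86 after saline.

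Whole kidneys were compared after 10 mg/kg and saline. Plk2 rose 37.4-fold, Ccl20 by 4.71 ± 0.72 and Isg20 by 4.60 ± 0.43 on the log2 scale. Kcns2, a potassium channel subunit gene, rose by 4.36 ± 0.48, Lcn2 17.8-fold, the transcription factor gene Egr2 by 4.004 ± 0.72, Gpx2 by 3.90 ± 0.35 and Guca2a, the guanylin gene, by 3.89 ± 0.44. The largest falls were in the amino acid transporter gene Slc7a12 (-5.27 ± 0.59), Oat, which encodes ornithine aminotransferase (-4.86 ± 0.38), the fructose transporter gene Slc2a5 (-4.35 ± 0.41), Slc6a13 (-4.13 ± 0.38), the choline dehydrogenase gene Chdh (-4.11 ± 0.87), Cubn, which encodes the endocytic receptor cubilin (-3.93 ± 0.40), Rgn (-3.79 ± 0.48) and Fhit (-3.77 ± 0.53). Havcr1 rose 12.7-fold and Cdkn1a by 2.93 ± 0.57, while Ccl2 had 2.32 ± 0.81 (limma adjusted p = 0.113) and Slc22a6 -0.89 ± 0.40 (limma adjusted p = 0.223).

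All 6 injury markers rose, S100a6 by 3.65 ± 0.51, Spp1 by 2.62 ± 0.58 and Anxa1 by 2.44 ± 0.42 among them (camera adjusted p = 1.66e-05, adjusted p = 0.151 with an estimated correlation). Spp1 lost its call without control whole kidney replicate 2 (2.25, limma adjusted p = 0.0648) and without 10 mg/kg whole kidney replicate 1 (2.40, limma adjusted p = 0.0556). Without scaling Anxa1, Klf6, Glud1 and Gsta2 lost theirs, with limma adjusted p between 0.0643 and 0.201. Egr2, Ier3 (2.67 ± 0.37) and Klf6 (2.14 ± 0.30), the 3 immediate early genes, rose (camera adjusted p = 0.00293, adjusted p = 0.108 with an estimated correlation). Of 21 carriers and brush border genes 14 fell, 17 when adjusted over the list alone (camera adjusted p = 0.130). Fbp1 fell by 3.29 ± 0.33 and the glutamate dehydrogenase gene Glud1 by 2.20 ± 0.36 among the 4 of 7 gluconeogenesis genes that fell, and 5 of 8 fatty acid oxidation genes fell, Cyp4a8 by 3.09 ± 0.49 and Amacr by 2.21 ± 0.29. Beside the rise of Gpx2, 5 of 6 Nrf2 and glutathione genes fell, among them Gstt2 (-2.39 ± 0.43), Gss (-2.36 ± 0.35) and Gsta2 (-2.00 ± 0.29). Psat1 fell by 2.64 ± 0.35, and Asns had -0.55 ± 0.45. All 3 named S3 markers fell, Slc3a1 (-3.32 ± 0.37) and Slc22a7 (-2.87 ± 0.55) among them, and the call of the remaining one, Gc, was lost without any 1 of the 6 whole kidney arrays (between -3.42 and -2.90, limma adjusted p between 0.0549 and 0.0930). Camera did not pass the gluconeogenesis, fatty acid oxidation, Nrf2 and glutathione, or S3 lists (camera adjusted p = 0.266, 0.266, 0.570 and 0.341). C1qa and C1qc were 2.44-fold and 2.84-fold higher without passing the threshold over all probes (limma adjusted p = 0.0753 and 0.0527), and 2 of 2 rose when adjusted over the list alone.

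The limma fit called 1717 probes in whole kidneys, 779 higher and 938 lower, and 56 named genes rose and 186 fell. Outside the authors' set of 1219 probes 610 rose and 559 fell. Groups did not overlap for 26.4% of probes, against 10% by chance where each group has 3 values and more where a value is missing. Without scaling the count was 356, with 107 higher and 249 lower, with median centring 675, and with only the 6 arrays compared 672. Without control whole kidney replicate 3, the array that stood apart, 1182 were called. In tubules and whole kidneys, which share no array, 300 probes rose and 336 fell in both at 10 mg/kg, against 19.3 and 31.5 for independent lists, and 2 moved in opposite directions. Among named genes 33 rose in both, 109 fell in both and 0 went opposite ways. Across all probes the fold changes correlated at r = 0.378 and rho = 0.287, with a covariance of 0.300 against 0.000425 simulated. The simulated groups held no change and shared no array, so their covariance was near 0 by construction.

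Control tubules were then compared with control whole kidneys. Slc5a2, the S1 sodium-glucose cotransporter SGLT2 gene, was 426-fold higher in tubules, at a log2 signal of 16.81 ± 0.34 (SD, n = 3) against 8.07 ± 0.83. The latter lay at the 47.5 percentile of all probes, and with no background measure it is not known to be above background, so the fold is a ratio of signals. The amino acid transporter gene Slc7a7 was 130-fold higher, and Epb41l3 (6.31 ± 0.63), Ddc, the dopa decarboxylase gene (5.49 ± 0.48), the bicarbonate cotransporter gene Slc4a4 (5.29 ± 0.42), Nox4 (5.08 ± 0.50), Dgkg (3.92 ± 0.41) and Add3 (3.50 ± 0.45) followed on the log2 scale. Lower in tubules were Osgin1 (-4.25 ± 0.56), Slc7a12 (-3.86 ± 0.59), Hnmt (-3.72 ± 0.67), Gc (-3.54 ± 0.80), Slc22a7 (-3.31 ± 0.55), S100a11 (-3.16 ± 0.44), S100a6 (-2.82 ± 0.51) and the transferrin gene Tf (-2.67 ± 0.46). Gc lost its call without control tubule replicate 2 (-3.09) or 3 (-3.05) and without control whole kidney replicate 1 (-3.55), 2 (-3.60) or 3 (-3.49), with limma adjusted p between 0.0608 and 0.108. S100a6 and Tf lost theirs without scaling (-1.83 and -1.64, limma adjusted p = 0.0921 and 0.152) and with only the 6 arrays compared. Gc lost its call with only these arrays too.

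By list, 5 of 7 S1 and S2 markers were higher in tubules (Slc5a2, Slc4a4, Spp2 at 10.6-fold and Gatm at 3.27 ± 0.47 among them, camera adjusted p = 0.00818) and 2 of 3 S3 markers lower (camera adjusted p = 0.0237), with an estimated correlation adjusted p = 0.478 for both. Of 21 carriers and brush border genes 8 were higher and 2 lower (camera adjusted p = 0.0775), with Slc7a9 at 3.50 ± 0.34. Slc34a1 was higher by 1.28 ± 0.29, a call lost with median centring (1.58), with cyclic loess (1.11), with only the 6 arrays compared (1.18), and without control tubule replicate 2 (1.30) or 3 (1.17) or control whole kidney replicate 1 (1.31) or 3 (1.14), with limma adjusted p between 0.0575 and 0.172. Of 7 gluconeogenesis genes 5 were higher, Sord by 2.09 ± 0.33 and G6pc1 by 2.97 ± 0.61 (camera adjusted p = 0.0178, adjusted p = 0.478 with an estimated correlation), and G6pc1 lost its call without control tubule replicate 3 (2.92, limma adjusted p = 0.0546) or control whole kidney replicate 2 (2.83, limma adjusted p = 0.0536), and Sord with only the 6 arrays compared (2.10, limma adjusted p = 0.0559). Of 6 injury markers S100a6 and Anxa2 (-2.13 ± 0.40, a call lost with median centring, without scaling and with only the 6 arrays compared at -1.71, -1.08 and -2.15) were lower (camera adjusted p = 0.0178, adjusted p = 0.478 with an estimated correlation). Slc22a5 was higher by 2.33 ± 0.27. No marker list of another kidney cell type could be read here except C1qa (0.40 ± 0.40) and C1qc (0.77 ± 0.43).

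The limma fit called 954 probes between the control tissues, 565 higher and 389 lower in tubules. With median centring the split was 558 to 239 and without scaling 1245 to 70. The count was 575, 573 and 572 without control tubule replicate 2, control tubule replicate 3 and control whole kidney replicate 3, and 265 with only the 6 arrays compared.

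**Figure D3:**
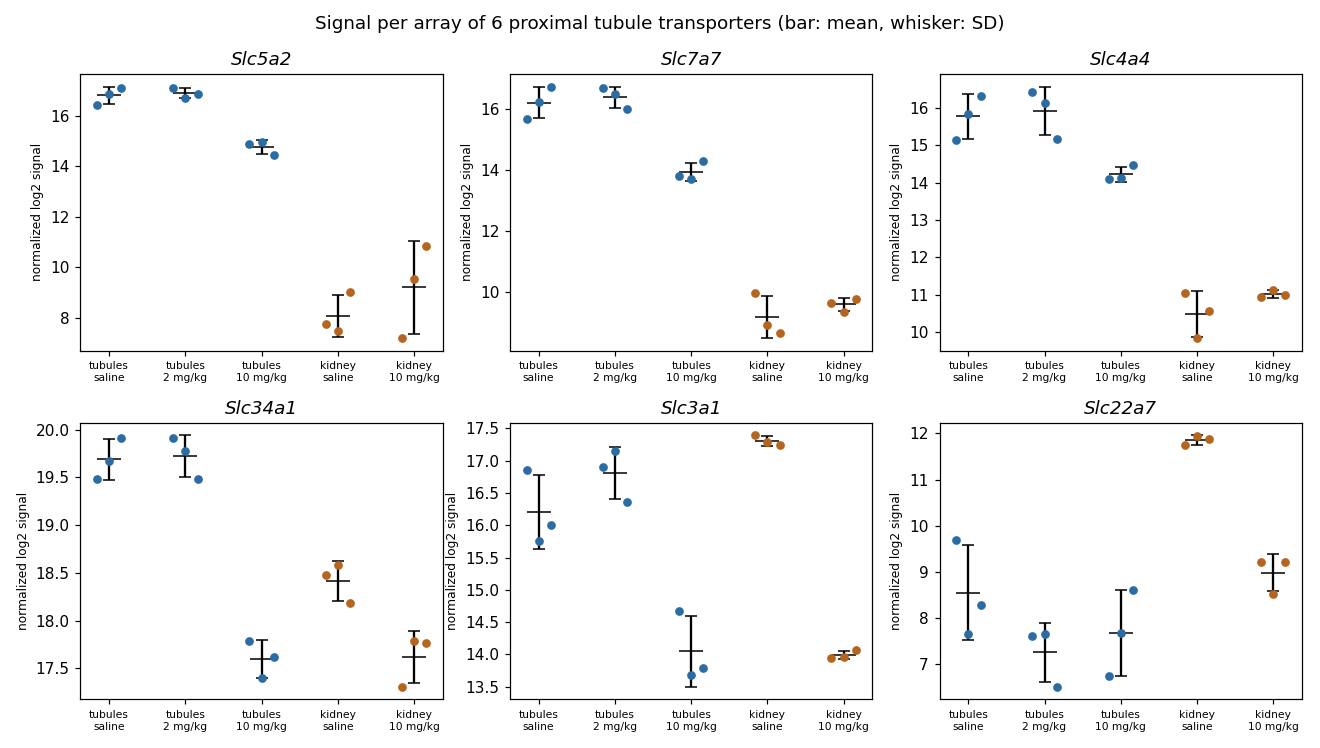
Normalized log2 signal (y axis) of 6 proximal tubule transporter genes in each of the 15 arrays by group (x axis), with the mean (bar) and SD (whisker) of 3 arrays. Slc5a2, Slc7a7 and Slc4a4 lay far lower in whole kidneys than in tubules, while Slc34a1 differed by 1.28 between the control tissues and Slc3a1 by -1.11.

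The effect of 10 mg/kg was finally compared between tubules and whole kidneys by the interaction contrast. Nrg1, which encodes the growth factor neuregulin 1, had a 2.82-fold higher mean after the drug in tubules (limma adjusted p = 0.107) and fell by 3.41 ± 0.49 in whole kidneys, a difference of 4.91 ± 0.70 (limma adjusted p = 0.0280). Asns rose by 4.02 ± 0.45 in tubules and had -0.55 ± 0.45 in whole kidneys, a difference of 4.57 ± 0.64 (limma adjusted p = 0.0280), with a signal percentile of only 8.73 in control tubules. Tnfsf13, which encodes the cytokine APRIL, had -0.90 ± 0.33 in tubules (limma adjusted p = 0.156) and rose by 2.24 ± 0.33 in whole kidneys, a difference of -3.14 ± 0.46 (limma adjusted p = 0.0313). Of the 36 calls of these 3 genes with 1 of the 12 arrays left out 25 were lost: Nrg1 kept its call only without control tubule replicate 1, tubule 10 mg/kg replicate 2 or whole kidney 10 mg/kg replicate 2 or 3, Asns only without these or without control whole kidney replicate 2 or whole kidney 10 mg/kg replicate 1, and Tnfsf13 only without whole kidney 10 mg/kg replicate 2. Over all alternatives the differences lay between 4.07 and 5.39, 4.08 and 4.99, and -3.55 and -2.85, with limma adjusted p of at most 0.164, 0.0943 and 0.221. The differences of Havcr1 (1.28 ± 0.58), Ccl2 (1.29 ± 1.15), Spp1 (0.52 ± 0.82), Cdkn1a (1.05 ± 0.81), Lcn2 (-1.13 ± 0.72) and Slc22a6 (-1.65 ± 0.56) did not pass the threshold (limma adjusted p between 0.310 and 0.876), and no list passed camera. The limma fit called 10 probes, 5 in each direction and 3 of them named, and the count fell to 0 without control tubule replicate 2, without tubule 10 mg/kg replicate 3 or without control whole kidney replicate 1. It was 1 without control tubule replicate 3, 3 without tubule 10 mg/kg replicate 1, 6 without control whole kidney replicate 3, 2 with median centring, 2 without scaling (0 of them higher) and 0 with only the 12 arrays compared. Other settings raised the count, among them the trended and robust variance model, as given with the processing alternatives. The series table's values raised it too, but cover only 1219 probes chosen by a rule not given.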

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

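The tests on Asns and Nrg1 and the bound for the count of other groupings were chosen after their values were seen. The interaction between tissue and drug was past the threshold for 10 probes in a direct test of whether the change at 10 mg/kg differed between tubules and whole kidneys. The named ones were Nrg1 (4.91 on the log2 scale, higher in tubules), Asns (4.57) and Tnfsf13 (-3.14). Over all alternatives their values stayed within 4.07 to 5.39, 4.08 to 4.99 and -3.55 to -2.85, with limma adjusted p of at most 0.164, 0.0943 and 0.221. Of 100 groupings drawn from 200 that keep each tissue's 6 arrays together, 6, the real one included, gave at least as many calls as the real one, so chance was not excluded for the count of 10. The highest of the 5 others gave 2996 calls. It exchanges the labels of the whole kidneys alone, which turns the change shared by both tissues into a difference, a structure of the samples, and the next highest gave 205.

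Asns and Nrg1, picked by their values with Tnfsf13 left out, moved apart between the tissues. Array scaling is argued against as the source of the size of their differences, the smaller of which was 4.07 at its lowest over 4 scalings. Their calls did depend on scaling, as neither gene passed the threshold without it. For a response of the tubules to being isolated, Nrg1 differed by -0.92 between control tubules and control whole kidneys (at most -0.52 with any array left out), so no rise showed. Other cells of the whole kidney enter that difference and could hide a rise, so the comparison does not decide. A handling effect on injured tubules alone was not tested. The response stays open for Asns too, which differed by -1.57 in the same comparison (at most -1.30 with any array left out) but was dim in control tubules, at a signal percentile of 8.73. Dilution of tubule RNA by other cells is argued against as the whole cause for Nrg1, which had higher means in tubules after the drug (by at least 1.09 with any array left out) and fell by 3.41 in whole kidneys (at most -3.09 with any array left out), a fall that diluting a rise cannot give. The higher mean in tubules did not pass the threshold and Nrg1 was picked by this difference, so the argument rests on the fall in whole kidneys. For Asns dilution cannot be told apart, because the injury and carrier genes were higher in tubules than in whole kidneys at 10 mg/kg by a median of 0.77 with an SD of 2.29 over 27 genes, against 3.001 for Asns, and blunting depends on a gene's level in other cells. A difference between the tubule's and the organ's response may underlie the values and stays open as a hypothesis.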

How the results depend on the processing

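Background correction with normexp and the restriction to the brighter probes were chosen after the data were seen, and the other alternatives before. The counts of probes past the threshold in tubules at 10 mg/kg, between the doses, in whole kidneys at 10 mg/kg and between control tissues were 1553, 1711, 1717 and 954, and stayed within a factor of 1.5 with cyclic loess, with no filter, over probes listed in all 15 files, with a 2-fold minimum, with treat and with normexp. Without scaling they were 917, 1010, 356 and 1315, and with median centring the count in whole kidneys was 675. With the series table's values over its 1219 probes they were 967 (193 higher), 956 (172 higher), 749 (212 higher) and 406 (327 higher), and 23 (13 higher) at 2 mg/kg, where fewer probes were tested. The series table's values are close to median-centred signals, so this setting differs from median centring mainly in its probes, chosen by a rule not given. With only the compared arrays, which leaves fewer degrees of freedom, the counts were 592, 998, 672 and 265. With a trended and robust variance model 2628 probes passed in whole kidneys and 1643 between control tissues, and with array weights 3085 between the doses. Over the brighter probes alone the counts were 2341, 2588, 2589 and 1689. The cause of the other shifts was not tested.

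The count of 10 for the tissue difference of the drug effect was the least stable: 2 with median centring, 2 without scaling, 176 (43 higher) with the series table's values, 305 with the trended and robust model, 17 with array weights, 0 with only the compared arrays, 16 with normexp and 169 over the brighter probes. The 176 came from nearly the same scaling as the 2 with median centring, over the authors' set of probes alone. With any 1 array left out the counts lay between 0 and 1 at 2 mg/kg, 995 and 1193 in tubules at 10 mg/kg, 962 and 1481 between the doses, 1170 and 1384 in whole kidneys, 572 and 792 between control tissues and 0 and 15 for the tissue difference. A group left with 2 arrays takes its spread from the pooled fit. At 2 mg/kg the count was 1 without 2 mg/kg replicate 3.

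With the replicate number as a block the count for the tissue difference was 0, and the counts of the other comparisons stayed within a factor of 1.5. The numbers do not pair the arrays: the deviations of same-numbered arrays correlated between -0.122 and 0.124, 1 of 30 pairs passed 0.1, and 3 of 15 arrays correlated best with their own number.

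Of the gene lists 3, 3, 2 and 4 passed camera in those 4 comparisons, and 0 in each with an estimated correlation. By fry, which compares no list with other genes, 12, 11, 12 and 8 passed, and 1 for the tissue difference. With an array left out the list count between control tissues lay between 2 and 5, with 2 without control tubule replicate 3, and the other list counts did not move. The correlation of fold changes between the doses lay between 0.205 and 0.383 with an array left out. Between tubules and whole kidneys it lay between 0.331 and 0.393, and was 0.422 with median centring.

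Of 188 values of named genes past the threshold 0 changed sign under any alternative. Their calls were lost for 47 with only the compared arrays, 38 without scaling, 21 with median centring, 14 with the block, 3 with cyclic loess, 1 with array weights and 0 with no filter, the series table's values, the trended and robust model or normexp. The series table's values are close to median-centred signals, fitted and adjusted over its 1219 probes alone. All named genes lie among these probes, so the 0 for this setting is no separate check of their calls. Signs changed for values that were not past the threshold. At 2 mg/kg Slc22a6 was 0.038 and Cdkn1a 0.17 with array weights. With an array left out Slc22a6 lay between -0.39 and 0.086, Lcn2 between -0.65 and 0.069 and Cdkn1a between -0.82 and 0.29. The tissue difference of Spp1 was -0.15 without scaling and with an array left out lay between -0.010 (without tubule 10 mg/kg replicate 3) and 1.32. No gene had a further named probe, so other probes of a gene and means over probes could not be compared.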

Other observations

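The tests of the tissue pattern, the bound for the other groupings and the use of the SE of the mean at 2 mg/kg were chosen after the results were seen, the other tests at 2 mg/kg before. Some transcripts stood between the groups at the lower dose without passing the threshold. Plk2 lay at a log2 signal of 8.57 ± 0.45 (SD, n = 3) after saline, 10.82 ± 0.32 at 2 mg/kg and 14.49 ± 0.19 at 10 mg/kg, and Asns at 6.21 ± 0.45, 7.94 ± 0.63 and 10.22 ± 0.12, the first at a signal percentile of 8.73 and not known to be above background. The lower-dose arrays lay above all control arrays for both, genes singled out after their values were seen. For Slc5a2, Slc7a7 and Slc4a4 the changes at 10 mg/kg in whole kidneys were 1.12 ± 0.69, 0.42 ± 0.39 and 0.53 ± 0.42 on the log2 scale, and in tubules -2.03 ± 0.69, -2.27 ± 0.39 and -1.55 ± 0.42, with interaction adjusted p from limma of 0.261, 0.0969 and 0.212.

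No probe was called in tubules at 2 mg/kg. A response as large as that to 10 mg/kg, hidden by the spread between arrays, is argued against: over the 1717 probes called in whole kidneys and signed by them, which share no array with the tubules, the mean change was -0.0856 at 2 mg/kg (between -0.127 and -0.0442 with any array left out) and 1.16 at 10 mg/kg. For a smaller shift of these probes as a set in the same direction, the bound set in advance against it was met: the mean lay below 0 with every array left out. It lay below 0 by more than its SE of 0.064 but by less than 2 SE, so a small shift is not excluded. The exact permutation test, two-sided over 3 against 3 arrays, gave p = 0.3, where 0.1 is the smallest possible, and decides nothing. Changes of a few genes, or of probes outside this set, may lie below the limit, as simulated 2-fold changes were called in 0.896% of cases.

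Slc5a2, Slc7a7 and Slc4a4 were more than 30-fold higher in control tubules than in control whole kidneys, and were picked by their values from a longer list in which Epb41l3 (6.31), Ddc (5.49) and Nox4 (5.08) were about as high. Array scaling is argued against, as the lowest of their differences was 5.26 over 4 scalings. For a smaller share of proximal tubule RNA in whole kidneys, the other 18 carriers and brush border genes had a median difference of 0.45 with an SD of 1.60. For a larger share of the S1 and S2 segments in the picked tubules, the other 5 markers had a median of 1.28 with an SD of 1.54, and 3 S3 markers had a median of -3.31. Both medians of the other genes lay below the lowest of the 3 by more than the SD. The picked genes were the largest of their lists, so that the others lay lower was fixed by the picking, and neither test decides on its cause. The other 18 ran from -1.85 to 3.50, so the carriers did not differ by 1 common amount. Picking of the earliest part of the tubule, or a difference in how both kinds of array were made, may contribute and was not tested.

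For the other comparisons the 6 arrays allow 10 groupings, too few for a share under the threshold. The real grouping gave 1553 calls in tubules at 10 mg/kg against 0 at most in the others, 1711 against 0 between the doses, 1717 against 6 in whole kidneys, 954 against 1 between control tissues, and 0 against 1 at 2 mg/kg. In each of the first 4 comparisons 1 of the 10 groupings, the real one, reached its count, and at 2 mg/kg all 10 did. The other groupings mix arrays of both real groups, so a real difference adds to their spread and lowers their counts. Low counts there do not show what unchanged groups would give.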
